A study of Neurospora crassa with 19 samples.

How the data were processed

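Poly-A RNA of Neurospora crassa strain N5801, labelled as a dim-1 deletion, was sequenced in 2 libraries. Per the labels' protocols, cultures grew for 16 h at 32 °C in minimal medium with 1.5% sucrose, RNA was extracted with phenol and glass beads and treated with DNase, and libraries were made with a stranded mRNA kit. The authors deposited whole-number counts of reads per gene for each library, without normalization. Per the submitters' processing notes, the tools of the series include Bowtie, Bowtie2, TopHat, SAMtools, HTSeq and DESeq, with no versions and no roles given. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be assigned with certainty. The reads carry no molecular identifiers that the labels name, so all intervals and floors cover counting error only.

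Each library listed 9730 genes by locus number, followed by 5 rows that HTSeq uses for reads without a gene. Those rows were left out of library sizes and tests. Reads outside any gene made up 6.72% of all rows in replicate 1 and 6.64% in replicate 2, reads aligned to several places 3.41% and 2.48%, and reads that fitted more than a single gene 0.0728% and 0.0771%. The rows for low alignment quality and for unaligned reads were 0 in both libraries. Over genes, replicate 1 held 17364963 counts (median 365 per gene) and replicate 2 held 13632746 (median 266). The limit that a count of 0 allows, 3 counts of the library, was 0.173 CPM in replicate 1 and 0.220 in replicate 2. No mitochondrial gene was among those counted.

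Gene symbols and the order of genes came from a RefSeq gene table of assembly NC12. It held 9729 of the 9730 loci, of which 1118 had a symbol other than the locus number. The locus of dim-1, NCU06484, is named in the series' labels. Since the build behind the counts is not stated, no coordinates from that table are given, and the table served for names, gene neighbours and, in checks of length, the span from gene start to gene end. Some list genes carry another symbol in the table (pfk is emp-3, pgi is gpi-1, ash-1 is set-3, npf is cac-3 and cox-5 is cya-4). The table does not give exon lengths, so the intended correction by exon length was replaced by gene span. No genome sequence was used here, so intended descriptions of genes beside AT-rich DNA and of genes within set distances of chromosome ends were not made.

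Levels are CPM over all gene counts, with the mean and SD over n = 2 replicates. Exact Poisson 95% intervals were set on the counts of dim-1. A gene was detected with at least 10 counts in both libraries. Agreement was described across genes with Pearson's and Spearman's correlation of log2(CPM + 1), a chi-square test of equal proportions over genes with reads, and the common dispersion of edgeR 4.0.16 with TMM scaling in R 4.3.3, whose square root is the coefficient of variation beyond counting error. With only 2 libraries of a single group, no quasi-likelihood test between groups could be fitted. For each gene with at least 20 counts in both libraries together, a two-sided exact binomial test set the replicate 1 reads against the TMM-scaled library share, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 and at least 2-fold. Log2 ratios are TMM-scaled with 0.5 counts added and are replicate 2 over replicate 1. edgeR's exact test with the common dispersion, estimated from the same libraries taken as replicates, was run as an alternative. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

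The 19 gene lists were fixed before the data were examined and cover 141 genes: DNA methylation and heterochromatin, histone H3 methylation, remodelers and assembly factors, histones, quelling, clock and light, carotenoid, conidiation, sexual development, strain background, quinic acid, nitrogen, plant cell wall degradation, glycolysis and fermentation, glyoxylate and gluconeogenesis, heat shock, oxidative stress, DNA repair, and constitutive genes. A member was dropped where the gene table gave its locus a symbol not accepted as another name of that member. This removed 2 members, swr1 (crf1-1 in the table) and qa-x (rhd in the table). A dropped member may still be the intended gene under another symbol. A further 12 lists were taken from symbol families of the gene table, without use of their values, after the planned lists by protein product could not be formed. For levels, the median of the detected members was set against 10000 random lists of as many detected genes, for lists with at least 3 such members. For ratios, the median over members with reads was set against 10000 random lists matched on mean expression in 20 bins. Genes named in the text are dim-1 and 2 neighbours on each side, the highest and lowest 2 members of each list, the 10 highest genes, the 10 genes with the largest ratio in each direction among called genes of at least 10 CPM, and the 5 highest genes near chromosome ends. Exceptions are said to be named after their values were seen. Some further genes of the symbol-family lists, such as gh28-2 and stk-36, were named because a test called them.

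The tests were tried on simulated libraries drawn from the real means and library sizes, with 200 genes changed 4-fold. At a coefficient of variation of 5%, 10% and 20%, the binomial test recovered 100%, 99.5% and 99.5% of the changed genes and called 6, 11 and 186 unchanged genes out of about 7900 tested. edgeR's exact test, with its spread estimated from the libraries that held the changed genes, recovered 99.5%, 97.0% and 66.5%. Changes below 4-fold and coefficients above 20% were not simulated. The coefficient estimated from separate simulated libraries without changed genes was 5.0%, 10.0% and 20.1%. Alternatives tried were DESeq2 1.42.0 size factors, total counts, other pseudocounts, other filters on low counts, all genes as background, division by gene span, removal of a trend with gene length, and each replicate alone.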

Results

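The series examined Neurospora crassa, a filamentous fungus, with and without a working dim-1 gene (NCU06484), which its title describes as a chromatin remodeler that keeps DNA methylation from appearing in the wrong places. Its 19 samples covered nuclei digested with micrococcal nuclease, bisulfite sequencing, chromatin immunoprecipitation for histone H3 lysine methylation, whole-genome sequencing and RNA. The values described here came from the 2 poly-A RNA libraries of strain N5801, labelled as a complete dim-1 deletion, and the other 17 samples were not analysed here. The strain was grown for 16 h at 32 °C in shaken Vogel's medium, a standard minimal medium, with 1.5% sucrose as the carbon source. The labels call the material germinated conidia, that is, growth from asexual spores. The wild-type RNA reference that the series names belongs to another series and was not used here, so no gene could be called higher or lower than in wild type. The libraries give the level of the targeted gene, the levels of gene groups in this strain, and the spread between replicates against which any such difference would be read. Replicate 1 held 17364963 counts over genes and replicate 2 held 13632746. The labels call the RNA data duplicate without saying whether the cultures were separate, so the spread between the replicates may be technical.

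The dim-1 gene had reads in both libraries labelled dim-1 deletion. Replicate 1 held 258 counts, or 14.9 CPM (counts-per-million of the library; exact 95% interval 13.1 to 16.8), and replicate 2 held 171 counts, or 12.5 CPM (10.7 to 14.6). The mean was 13.7 ± 1.64 CPM (SD, n = 2), and the 2 libraries did not differ at this gene by the exact binomial test on reads (log2 ratio −0.19, adjusted p = 0.261). Among detected genes dim-1 stood at percentile 29.3 in replicate 1 and 28.2 in replicate 2. Per kilobase of gene span its level was 1.92 CPM in replicate 1, against a median of 13.3 over detected genes, and 1.62 against 12.5 in replicate 2, at percentiles 9.17 and 9.41. Of the 2 genes on each side, NCU16634 had 77.8 ± 6.17 CPM, NCU06483 had 96.0 ± 9.25, NCU06485 had 12.9 ± 4.09 and the kinase gene stk-43 (NCU06486) had 2.02 ± 0.158 (SD, n = 2). Counts per gene do not show which part of dim-1 the reads came from, so they check the label only in part, and the libraries are therefore named by their label.

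The mating-type genes mat A-1 (NCU01958), mat A-2 (NCU01959) and mat A-3 (NCU01960) had 0 counts in both libraries, which allows up to 0.173 CPM in replicate 1 and 0.220 in replicate 2. The precursor of the pheromone made by the opposite mating type, mfa-1 (NCU16992), had 232 and 128 counts (11.4 ± 2.81 CPM; SD, n = 2). The precursor of the pheromone made by mating type A, ccg-4 (NCU02500), named after its values were seen, had 33 and 19 counts. The end-joining gene mus-51 (NCU08290), inactivated in the strains in which many Neurospora knockouts were made, had 7 and 10 counts. Its partner mus-52 (NCU00077) had 563 and 352 counts, or 29.1 ± 4.67 CPM, and the histidine gene his-3 (NCU03139) had 296 ± 29.6 CPM.

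Of the 10 most abundant transcripts, 4 belonged to alcoholic fermentation or glycolysis. Pyruvate decarboxylase, cfp (NCU02193), led with 19352 ± 6315 CPM (SD, n = 2). The glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, gpd-1 (NCU01528), had 15520 ± 2649 CPM, alcohol dehydrogenase adh-1 (NCU01754) had 10193 ± 2726 and enolase emp-7 (NCU10042) had 5990 ± 1428. The other genes among the 10 highest were NCU06110 (13155 ± 3114), the thiamine-related gene nmt-1 (NCU09345; 12813 ± 4089), the translation elongation factor tef-1 (NCU02003; 9257 ± 70.8), the clock-controlled gene ccg-14 (NCU07787; 7569 ± 3379), NCU05498 (6850 ± 314) and the clock-controlled gene ccg-15 (NCU08936; 5385 ± 974). The 10 highest genes of a library held 9.66% of its counts in replicate 1 and 11.8% in replicate 2. Of 9730 genes, 7775 (79.9%) were detected with at least 10 counts in both libraries and 772 had 0 counts in both. The median detected gene had 34.2 CPM, and 177 genes exceeded 1000 CPM.

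Genes of DNA methylation and heterochromatin were all detected, with a middling list median. The 13 members had a median of 31.2 CPM, at percentile 42.6 of 10000 random lists of as many detected genes (19.65 when levels were divided by gene span). The adaptor gene dim-3 (NCU01249) was highest at 244 ± 9.77 CPM (SD, n = 2), followed by cul4 (NCU00272), the cullin of the complex that directs histone H3 lysine 9 methylation, at 62.9 ± 1.24. The lysine 9 methyltransferase gene dim-5 (NCU04402) was lowest at 5.82 ± 2.11 CPM, followed by dim-7 (NCU04152) at 17.6 ± 0.464. The 8 other histone H3 methylation genes had a median of 20.97 CPM (percentile 20.8), from 2.13 ± 0.414 for eed (NCU05300) and 9.30 ± 1.68 for suz12 (NCU05460), both of Polycomb repressive complex 2, to 45.6 ± 2.72 for ash-1 (NCU01932) and 65.7 ± 2.69 for npf (NCU06679). Divided by gene span, this list stood at percentile 2.36, with a median span of 4092 bases. The 6 remodelers and assembly factors had a median of 56.6 CPM (percentile 75.1, or 37.85 by span), with ino80 (NCU08919) at 142 ± 11.3 and chd1 (NCU03060) at 83.5 ± 10.6, and with csw-1 (NCU09106) at 23.0 ± 2.06 and acf1 (NCU00164) at 30.2 ± 3.85. The 8 histone genes stood far above them, with a median of 945 CPM that no random list exceeded (percentile 100). Histones hH3 (NCU01635) and hH2B (NCU02435) had 2266 ± 228 and 2146 ± 662 CPM, against 145 ± 22.7 for the variant hH2Az (NCU05347) and 30.5 ± 3.25 for the centromeric cenH3 (NCU00145). Whether reads of hH4-1 and hH4-2 align to both genes was not tested. The 6 genes of quelling, the RNA interference pathway of vegetative cells, had a median of 23.0 CPM (percentile 26.8, or 6.55 by span), from 17.0 ± 3.72 for the helicase gene qde-3 (NCU08598) and 17.2 ± 0.188 for qip (NCU00076) to 55.3 ± 2.95 for the Dicer gene dcl-1 (NCU08270) and 164 ± 26.6 for the Argonaute gene qde-2 (NCU04730). The 8 DNA repair genes had a median of 23.0 CPM (percentile 24.8, or 8.94 by span), with the checkpoint kinase prd-4 (NCU02814) at 69.7 ± 5.83 and mus-9 (NCU11188) at 53.2 ± 12.8, and with uvs-2 (NCU05210) at 3.72 ± 0.450 and msh-2 (NCU02230) at 15.9 ± 2.12. These percentiles depend on the background: against all genes they were 72.55 for DNA methylation, 47.28 for histone H3 methylation, 86.46 for remodelers, 49.74 for quelling and 51.35 for DNA repair.

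Genes of light responses, the clock and pigment were well expressed. The 11 clock and light genes had a median of 126 CPM (percentile 99.3), led by the photoreceptor gene vvd (NCU03967) at 1270 ± 90.7 CPM (SD, n = 2) and the kinase gene ck-1a (NCU00685) at 742 ± 68.8. The lowest were the helicase gene frh (NCU03363) at 40.7 ± 12.1 and the photoreceptor partner wc-2 (NCU00902) at 54.1 ± 1.56. The list stood at percentile 89.6 once levels were divided by gene span. The 5 carotenoid genes had a median of 230.0 CPM (percentile 99.1), from 48.3 ± 17.3 for cao-2 (NCU11424) and 169 ± 23.3 for al-3 (NCU01427) to 306 ± 12.4 for al-2 (NCU00585) and 762 ± 5.55 for al-1 (NCU00552).

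Genes of sexual development, quinic acid use and plant cell wall degradation stood low among detected genes as lists, although some members did not. Of 8 sexual development genes, 6 were detected, with a median of 3.40 CPM (percentile 0.12). The highest were fsd-1 (NCU09915) at 23.5 ± 4.66 CPM (SD, n = 2) and mfa-1, while fmf-1 (NCU09387) had 0 counts in both libraries and sad-1 (NCU02178), a gene of meiotic silencing, had 3 and 2 counts. The 6 quinic acid genes had a median of 6.32 CPM (percentile 1.21), with the permease gene qa-y (NCU06026) at 22.3 ± 3.28, the repressor gene qa-1S (NCU06027) at 14.4 ± 5.31, qa-3 (NCU06025) at 2.55 ± 0.753 and qa-4 (NCU06024) at 1.20 ± 0.251. Against all genes rather than detected genes, this list stood at percentile 13.78, the plant cell wall list at 17.49 and the sexual development list at 4.59. Of 11 plant cell wall degradation genes, 9 were detected, with a median of 9.29 CPM (percentile 2.41). The cellodextrin transporter gene cdt-1 (NCU00801) had 138 ± 78.8 CPM and the regulator gene clr-1 (NCU07705) had 47.3 ± 13.2, while gh3-4 (NCU04952) had 20 and 3 counts and gh10-2 (NCU08189) had 2 and 0. The 8 conidiation genes lay in the middle, with a median of 37.3 CPM (percentile 53.4). They ran from acon-3 (NCU07617) at 1.01 ± 0.285 CPM and con-6 (NCU08769) at 1.63 ± 0.597 to con-8 (NCU09235) at 106 ± 54.2 and csp-2 (NCU06095) at 112 ± 38.1.

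Genes of central metabolism and protein folding stood high as lists, less so for nitrogen genes by gene span. The 10 glycolysis and fermentation genes had a median of 3258 CPM (percentile 100), and even the lowest, the isomerase gene pgi (NCU07281) and the phosphofructokinase gene pfk (NCU00629), had 876 ± 221 and 973 ± 343 CPM (SD, n = 2). The 5 genes taken as constitutive had a median of 1559 CPM (percentile 100), with tef-1 and the proton pump gene pma-1 (NCU01680; 3151 ± 422) highest and cox-5 (NCU05457; 319 ± 70.0) and the tubulin gene bml (NCU04054; 879 ± 192) lowest. The 6 heat shock genes had a median of 491 CPM (percentile 99.97), with hsp70-1 (NCU09602) at 2096 ± 196 and hsp80 (NCU04142) at 938 ± 14.01, and with hsp30 (NCU09364) at 37.5 ± 3.28 and hsp60 (NCU01589) at 192 ± 67.9. The 4 glyoxylate and gluconeogenesis genes had a median of 270 CPM (percentile 98.6), from 78.5 ± 9.21 for acu-9 (NCU10007) and 173 ± 53.96 for acu-3 (NCU04230) to 368 ± 19.6 for acu-5 (NCU06836) and 1071 ± 241 for acu-6 (NCU09873). The 5 oxidative stress genes had a median of 100.0 CPM (percentile 92.4, or 89.13 by span), with the catalase gene cat-2 (NCU05770) at 812 ± 196, the superoxide dismutase gene sod-1 (NCU02133) at 690 ± 294, cat-1 (NCU08791) at 98.6 ± 13.5 and cat-3 (NCU00355) at 65.4 ± 15.8. The 7 nitrogen genes had a median of 86.2 CPM (percentile 92.6, or 70.1 by span), with nitrite reductase nit-6 (NCU04720) at 619 ± 124, glutamine synthetase gln-1 (NCU06724) at 482 ± 55.1, nitrate reductase nit-3 (NCU05298) at 39.9 ± 15.8 and the regulator gene nit-4 (NCU08294) at 15.3 ± 0.721. Levels compared across genes depend on transcript length, and the percentiles describe these libraries without a test.

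**Figure D1:**
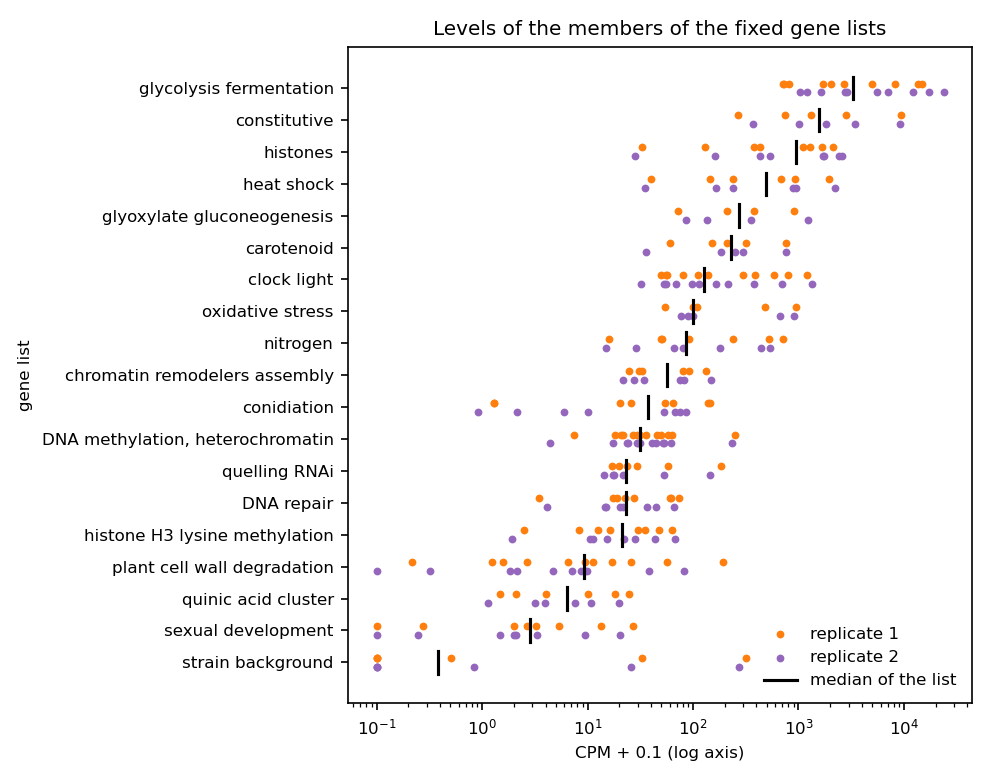
Levels of the members of the 19 fixed gene lists, in CPM plus 0.1 on a log axis, with a point per gene for each of the 2 libraries and a bar at the list's median over all members. The glycolysis and fermentation list has the highest median (3258 CPM) and the sexual development list is the lowest of those with at least 3 detected genes.

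The 2 libraries ranked genes alike but were not interchangeable. Across the 9730 genes, log2(CPM + 1) correlated with Pearson's r = 0.988 and Spearman's rho = 0.985. These describe genes, which are not independent replicates. The median absolute log2 ratio over detected genes was 0.28, and 5.75% of them differed by over 2-fold. The common coefficient of variation beyond counting error, estimated with edgeR, was 23.5%. The counts of the 2 libraries differed by far more than sampling noise (chi-square 97.8 per degree of freedom over 8957 degrees). They were therefore treated as separate libraries and not as a single library sequenced again. The value decides no more than that, because separate libraries differ by more than counting noise in any case.

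Some genes differed strongly between the replicates of this strain. In replicate 2, NCU04697 was 15.6-fold higher (1.61 against 24.7 CPM), NCU09648 6.23-fold, NCU03696 4.67-fold and the cytochrome c gene cyc-1 (NCU01808) 4.25-fold (229 against 941 CPM). The next were NCU09782 and the developmental regulator gene adv-1 (NCU07392), both at 3.13-fold, NCU09497 at 2.77-fold, NCU04496 at 2.76-fold, NCU04805 at 2.75-fold and NCU04039 at 2.67-fold. In replicate 1, NCU05897 was 10.8-fold higher (679 against 60.7 CPM), NCU09906 9.48-fold, NCU07033 8.06-fold, NCU09832 7.39-fold and NCU07840 7.28-fold. The polyketide synthase gene pks-5 (NCU09638) was 7.19-fold higher there, NCU08223 7.18-fold, NCU00855 7.07-fold, NCU09170 6.63-fold and the cell wall protein gene ncw-5 (NCU00716) 6.11-fold (1485 against 235 CPM). These genes were picked for the size of the difference between single libraries, which has no replicate check.

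Over 7898 genes with at least 20 counts in both libraries together, 4522 had an adjusted p under 0.05 by the exact two-sided binomial test. Of those, 486 also differed at least 2-fold and were called, 398 higher in replicate 1 and 88 higher in replicate 2. edgeR's exact test, with a common spread estimated from the same 2 libraries, called 51 of these 486 genes, 47 higher in replicate 1 and 4 in replicate 2. In that test even ccg-1 (NCU03753), at 3.38-fold with 10134 and 2271 counts, had an adjusted p of 0.0598. Smaller folds were therefore mostly beyond its reach. The binomial test compares these 2 libraries, not conditions, and treats reads as independent. In simulated libraries with a coefficient of variation of 20%, below the 23.5% estimated for these libraries, it called 186 unchanged genes. All 486 are differences between replicates of the same strain, and the simulation does not set how many exceed ordinary spread.

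**Figure D2:**
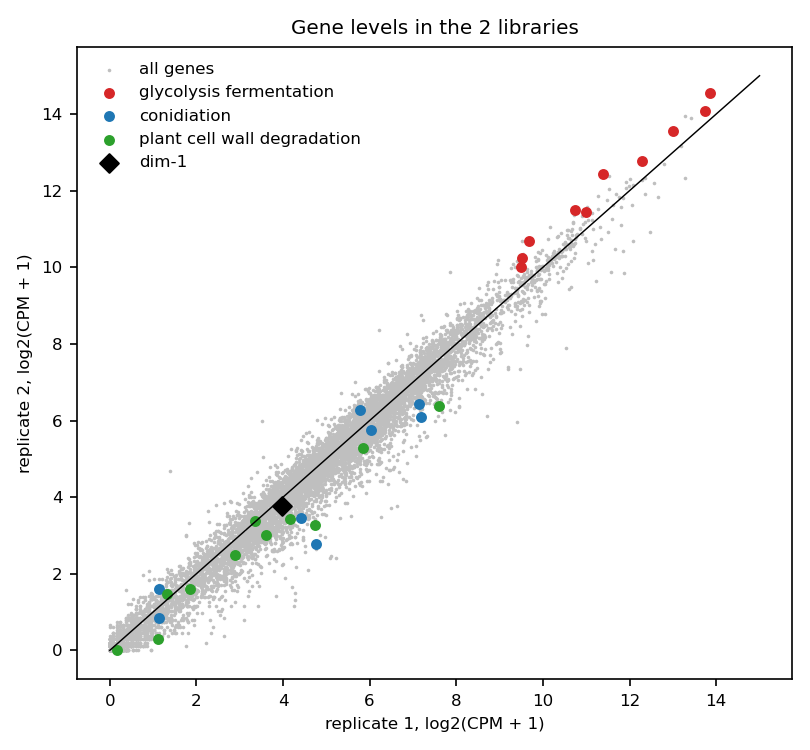
Level of each gene in replicate 1 (x axis) and replicate 2 (y axis), as log2(CPM + 1), with a point per gene and a line of equal levels. The 10 glycolysis and fermentation genes lie above the line, and dim-1 (diamond) lies near it at 14.9 and 12.5 CPM.

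Glycolysis and fermentation genes were higher together in replicate 2. All 10 members had a higher level there under each scaling, with a median log2 ratio of 0.67 (1.59-fold) that no random list of genes with matched expression exceeded (percentile 100). Of these, 2 were called by the exact binomial test: aldolase fba (NCU07807) at 2.13-fold and triosephosphate isomerase tpi (NCU07550) at 2.08-fold, both named after their values were seen. For cfp the ratio was 1.66-fold and for gpd-1 1.32-fold, below the 2-fold minimum. The count adjusted over the list alone was also 2, because the 2-fold minimum and not the adjustment limited it. edgeR's exact test called 0, which decides little at folds of this size.

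The medians of the conidiation and plant cell wall degradation lists were higher in replicate 1. The 8 conidiation genes had a median log2 ratio of −0.58 (1.49-fold; percentile 0.57), with 6 of 8 higher in replicate 1. The other members, eas (NCU08457), named after its values were seen, and con-6, were 1.47-fold and 1.75-fold higher in replicate 2, con-6 with 21 and 28 counts. The exact binomial test called con-8 at 2.06-fold and con-10 (NCU07325), named after its values were seen, at 4.24-fold (25.9 against 5.87 CPM). edgeR's exact test called con-10 alone. Of the 11 plant cell wall degradation genes with reads, 9 were higher in replicate 1, with a median of −0.60 (1.52-fold; percentile 1.06). Over the 9 detected members, which leaves out gh10-2 and gh3-4, the median was −0.52 at percentile 1.93. The exact binomial test called cdt-1 at 2.27-fold, the regulator gene xlr-1 (NCU06971), named after its values were seen, at 2.85-fold, and gh3-4, with 20 and 3 counts. edgeR's exact test called 0 of those, which decides little at the folds of cdt-1 and xlr-1. The counts adjusted over each list alone were also 2 and 3, because the 2-fold minimum and not the adjustment limited these calls.

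The 5 constitutive genes had a median log2 ratio of 0.50 (percentile 97.57) and all were higher in replicate 2, except that tef-1 turned lower when total counts set the scale. With at least 10 counts required of the random genes too, the median stayed at 0.50 and the percentile was 97.25. Once the trend with gene length was removed the median was 0.44 and the percentile 95.94, so the median changed little while the percentile passed inside the central 95% in both cases. Its median of 0.50 equals the upper limit of its random lists, so it lay on the edge of the central 95%. Thus 3 of 19 fixed lists lay beyond that range, or 4 with the constitutive list counted, against 0.95 expected by chance alone. That expectation holds only if the genes within a list vary independently of each other between libraries, as in the random lists. This was not tested, and genes that vary together would raise the expected number.

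The chromatin lists stayed inside that range, the histone list only barely. The DNA methylation and heterochromatin genes had a median log2 ratio of 0.01 (percentile 52.4), which was −0.04 when total counts set the scale. Medians were −0.10 for histone H3 methylation (percentile 35.3) and −0.03 for remodelers (33.8), which turned to 0.08 and 0.12 with the length trend removed. They were −0.32 for quelling (4.96, with 5 of 6 higher in replicate 1) and −0.27 for DNA repair (7.53), which shrank to −0.13 (19.29) and −0.14 (19.01) with the length trend removed. Histone genes reached 0.36 (percentile 97.48), with 7 of 8 higher in replicate 2 and none called. The clock and light list had a median of −0.15 (6.61), with 1 called gene, ccg-1 (NCU03753), at 584 CPM in replicate 1 and 167 in replicate 2 (3.38-fold). The median of that list was 0.01 with the length trend removed. In the sexual development list (−0.35, percentile 21.9) the exact binomial test called the pheromone receptor gene pre-2 (NCU05758) at 2.64-fold, higher in replicate 1. Both ccg-1 and pre-2 were named after their values were seen, and edgeR's exact test called 0 genes in either list. No member was called in the lists of carotenoid (0.07, percentile 50.4), quinic acid (−0.30, 24.1), nitrogen (−0.18, 9.91), glyoxylate and gluconeogenesis (0.12, 57.4), heat shock (0.16, 71.9), oxidative stress (0.06, 48.3) and strain background genes (−0.15, 31.1). The counts adjusted over each list alone were the same, again because the 2-fold minimum limited the calls.

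**Figure D3:**
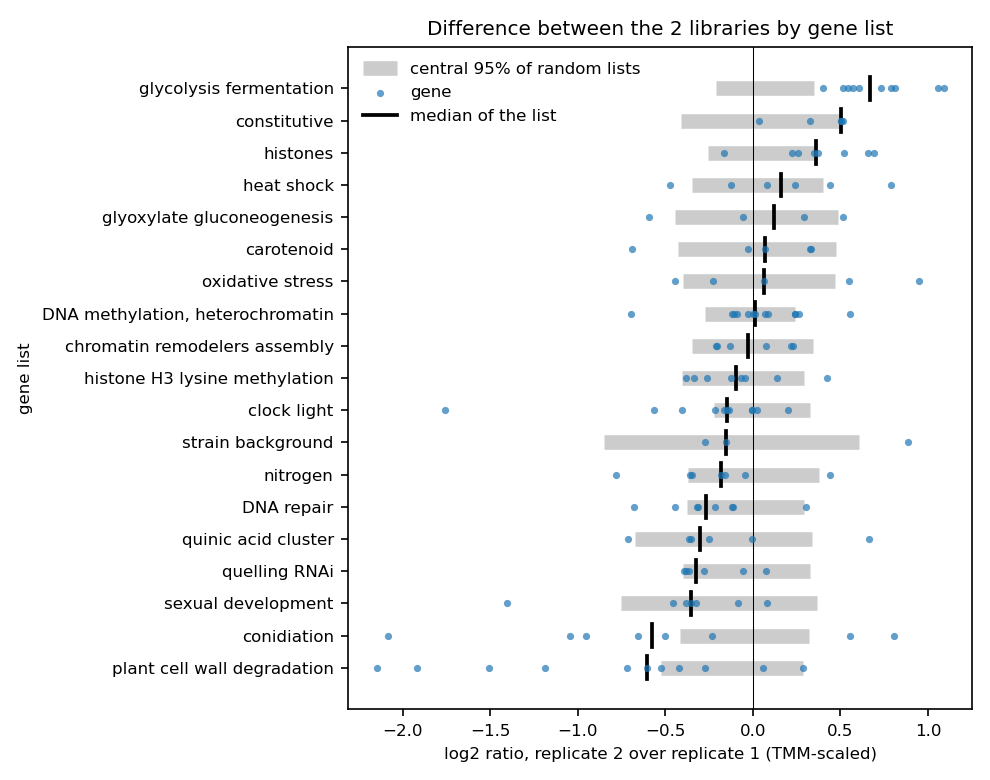
Log2 ratio of replicate 2 over replicate 1 for the fixed gene lists, with a point per gene, a black bar at the list's median and a grey bar over the central 95% of 10000 random lists matched on expression. The glycolysis and fermentation median (0.67) lies right of its grey bar, and the conidiation (−0.58) and plant cell wall degradation (−0.60) medians lie left of theirs.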

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

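Reads outside the genes counted appeared in both libraries labelled dim-1 deletion, in rows that no comparison above uses. Reads that fell in no annotated gene were 6.72% of all rows in replicate 1 (Wilson score 95% interval 6.71 to 6.74) and 6.64% in replicate 2 (6.63 to 6.65). Reads that aligned to several places were 3.41% in replicate 1 (3.40 to 3.41) and 2.48% in replicate 2 (2.47 to 2.49). No control library was analysed here to set against these shares, so they say nothing about the deletion. The files do not give the places these reads came from, so repeats and transcripts outside genes are not described.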

How the results depend on the processing

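Other scalings left dim-1 at 13.7 CPM, and the detected genes ranged from 6921 to 8569 across filters. Genes at chromosome ends stayed at percentile 0 with 10 or 40 genes per end, by gene span, with a match on gene length and in either replicate alone, and other scalings were not tried for them. Across alternatives, 6 to 9 fixed lists stood at or above percentile 95 and 2 to 4 at or below percentile 5, with the clock and light list leaving the first group and histone H3 methylation joining the second on division by gene span. With all genes as background, nitrogen and oxidative stress joined the first group, quinic acid (13.78) and plant cell wall degradation (17.49) left the second, and strain background (1.07) entered it. Gene span, the removal of a trend with gene length and the chromosome ends were added after the data were seen. With a single replicate, dim-1 stood between 12.5 and 14.9 CPM, the detected genes numbered 7811 to 7980, 7 fixed lists stood at or above percentile 95 and 3 at or below percentile 5. The correlation across genes moved from 0.988 to 0.984 with 10 CPM added in place of 1 CPM and to 0.976 over detected genes only. The coefficient of variation moved from 23.5% to 23.8% without a filter on low counts and to 22.8% with a mean of at least 10 CPM. For single lists, 34 level percentiles moved by more than the SD between the percentiles of the 2 replicates. The cause of these shifts was not tested.

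The count of genes that differ between the libraries depended on the test. It fell from 486 to 281 with a mean of at least 10 CPM, where 6019 instead of 7898 genes were tested, and all 281 are among the 486. It fell to 51 with edgeR's exact test, which adds the common spread between the libraries to counting error. DESeq2 size factors gave 486 and total counts gave 500, with 434 higher in replicate 1 and 66 in replicate 2. Among single gene lists, the difference of the constitutive list left the outer 5% under 2 settings. No called value changed sign, but medians of fixed lists near 0 did: DNA methylation with total counts, and histone H3 methylation (0.08), remodelers (0.12), and clock and light (0.01) with the length trend removed. The AT-rich and distance-based descriptions and the correction by exon length were not run. No paired analysis was possible because the libraries form a single group, with no other group to share replicate numbers. Depth limits calls among genes near the floor of 0.173 and 0.220 CPM, where gh10-2, with 2 and 0 counts, has no usable ratio.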

Other observations

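The medians of several lists of metabolism and proteolysis were higher in replicate 2, although no member of them was called higher there by either exact test. These lists were formed from gene symbols after the data were in hand, without use of the values. All 29 genes of respiratory complex I were higher in replicate 2 (median log2 ratio 0.33, percentile 99.56 of random lists matched on expression), as were all 14 of the vacuolar ATPase (0.43, 99.72), under either scaling. With the trend of gene length removed, complex I had a median of 0.22 at percentile 90.27, inside the central 95%, and the vacuolar ATPase had 0.37 at 99.22. Of 30 proteasome genes, 29 were higher there (0.35, 99.98). The exception was rpn-4 (NCU01640), named after its values were seen, which shares the prefix of the proteasome subunits and which the exact binomial test called 2.04-fold higher in replicate 1. Of 16 tricarboxylic acid cycle genes, 14 were higher in replicate 2 (0.33, 99.15), and of 21 mitochondrial protein import genes, 18 were (0.39, 99.98), or 17 with total counts as the scale. The proteasome, tricarboxylic acid cycle and import lists stayed at percentile 99.8 or above with the length trend removed. Peroxins had a median of 0.20 (95.8), arginine synthesis genes 0.17 (79.2), with arg-13 (NCU02802) called 2.69-fold higher in replicate 1, and polyketide synthases −0.47 (10.6), with pks-5 called, or −0.15 (38.3) with the length trend removed. The 50 stk kinase genes with reads had a median of −0.10 (4.45) and 1 call, stk-36 (NCU05658), with 29 and 9 counts. That median was 0.04 (47.0) with the length trend removed. The 9 cytosolic ribosomal protein genes found by symbol had a median of 0.01 (percentile 27.3), or −0.04 with total counts as the scale.

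Among cell wall protein and glycoside hydrolase genes, more were higher in replicate 1 than in replicate 2. Of 17 cell wall protein genes, 11 were higher there (median −0.29, percentile 0.29) and 4 were called by the exact binomial test: ncw-5 at 6.11-fold, ncw-1 (NCU05137) at 2.88-fold, acw-12 (NCU08171) at 2.53-fold and acw-4 (NCU09263) at 2.17-fold. Of 74 glycoside hydrolase genes with reads, 49 were higher in replicate 1 (median −0.27, percentile 0.59) and 6 were called, among them gh28-2 (NCU06961) with 70 and 5 counts, and gh3-4, which the plant cell wall degradation list also holds. Over the 56 detected members, which leaves out those with few counts and also gh28-2 and gh3-4, the median was −0.19 at percentile 1.18. Of these lists, edgeR's exact test called only ncw-5, gh28-2 and pks-5. In level, cell wall protein genes had a median of 860.0 CPM and the 9 ribosomal protein genes found by symbol 1130 CPM, with acw-8 (NCU07277) at 2879 ± 969 CPM (SD, n = 2) and ubi::crp-6 (NCU04553) at 1600 ± 83.7. Complex I genes had a median of 238 CPM, the vacuolar ATPase 240, the tricarboxylic acid cycle 368, the proteasome 163, protein import 72.6, arginine synthesis 69.7 and peroxins 49.0. Detected stk kinases had 50.6, polyketide synthases 30.9 and glycoside hydrolases 20.1.

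Of the tests that follow, those of scaling, counting noise, the length trend behind the glycolysis list and both tests of the dim-1 reads were chosen after the results were seen, as was the choice of genes at chromosome ends. The gene lists that differ between replicates of the same strain are the first pattern. A single scaling factor moves all lists alike, yet the highest and lowest list medians lay 1.27 apart on the log2 scale. Simulated counting noise gave as large a list median in 0 of 100 simulations, which decides nothing, because separate libraries differ by more than counting noise in any case. A trend with gene length, in which the longest 10% of detected genes had a median log2 ratio of −0.18 and the shortest 10% had 0.06, left 75% of the 4 lists at or beyond the limits of their range outside once removed, and the glycolysis and fermentation list at percentile 100, so length is not the whole of the pattern. The constitutive list kept a median of 0.44 of its 0.50 while its percentile passed inside the range, which leaves the part of length there open. No biological explanation was tested, since both libraries belong to 1 group.

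Reads at dim-1 in libraries labelled as its deletion are the second pattern. Background reads spread evenly over genes would set a floor for every gene, yet 19.1% of genes, 1863 of 9729 with a known span, lay more than 3-fold below dim-1 in CPM per kilobase in both libraries. This argues against an even background and leaves an uneven one open. The 429 counts over both libraries could come from gene ends that a replacement left in place, from neighbours, or from an intact gene, and counts per gene cannot tell these apart. No wild-type level was analysed here to set them against.

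Low levels of genes at chromosome ends are the third pattern. The outermost 20 genes at each of 14 chromosome ends, 280 genes by gene order, had a median of 8.77 CPM against 20.8 for all other genes, below all 10000 random gene sets (14.9 to 27.8 for their central 95%). The random sets are not runs of neighbours, so their range is too narrow if neighbouring genes have similar levels, which was not tested. Gene length does not account for the low median of the end genes, since that median was at percentile 0 among sets matched on gene length too. Of these genes 75.7% were detected, against 80.03% of the others, and the highest were the mitochondrial carrier gene aac (NCU09477; 3589 ± 933 CPM; SD, n = 2), NCU10040 (2977 ± 1872), NCU09476 (1968 ± 158), NCU10028 (554 ± 21.7) and NCU10572 (531 ± 253). Reads that align to several places were not counted to genes and may lower repeated genes there, which these counts leave open. No biological explanation was tested. The series' samples of histone H3 methylation in this strain, which could bear on it, were not analysed here.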
